A study of Homo sapiens with 6 samples.

How the data were processed

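The deposited values are whole-number counts per gene for 6 libraries of 786-O cells, in a table of 60649 genes named by versioned Ensembl ID and symbol. Per the labels, total RNA was extracted with TRIzol, libraries were made with an Abclonal kit and sequenced paired-end on an Illumina instrument. Per the submitters' processing notes, the authors checked reads with FastQC 0.11.9, trimmed them with Trim Galore 0.6.7, aligned them to hg38 with HISAT2 2.2.1 and used StringTie 2.2.1 before the counts were made. The tool that counted the reads, the annotation release, the strand setting, the selection of RNA and the treatment of reads that map to several genes are not given in the sources used here. Genes with a count of 2 were nearly as many as genes with a count of 1 (1470 to 1774 against 1632 to 2007 per library), and genes with a count of 3 were fewer (815 to 969), so an uneven step among low counts is present in the values. Reads were not used here. Gene positions, types, overlaps, exon lengths and GC content come from GENCODE 29 on GRCh38, which holds 58381 (96.3%) of the gene IDs, and 2 list genes were matched by gene ID rather than symbol. NPBWR1 has no position there.

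The labels name 3 groups of 2 libraries: shRNA1 and shRNA2 against LINC02068, and shControl. Nothing in them pairs replicates across groups or says that replicates are separate cultures, and no batch, date or passage is given, so replicate number was not used as a block. Groups, contrasts, the main test, gene lists, naming rule and most alternative settings were set before the data were examined.

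Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and mgcv 1.9.3. Genes passed filterByExpr by group (16039 genes), libraries were scaled by TMM, and group means were fitted with edgeR's quasi-likelihood model (robust, no intercept, all 6 libraries sharing their dispersion estimates). Contrasts were shRNA1 against shControl, shRNA2 against shControl, the mean of both hairpins against shControl, and shRNA1 against shRNA2. Genes with a Benjamini-Hochberg adjusted p under 0.05 in the F test were called. Levels are CPM over TMM-scaled library sizes, as group means. Intervals of single levels are 95% exact Poisson intervals. Bootstrap intervals of list medians resample the member genes (2000 draws). They treat genes as independent and leave out the spread between libraries. A group with no counts was set to a floor of 3 counts over the group (0.0882 CPM in shRNA1, 0.0527 in shRNA2, 0.0643 in shControl), and its fold is given as a lower bound.

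The 41 gene lists cover respiratory chain, mitochondrial, metabolic, stress, signalling, cell cycle, matrix, drug-related and histone genes and markers of other cell types. Lists with at least 5 tested members (38) were tested with limma's camera on log2 CPM (prior count 2). It used a preset correlation of 0.01, and p-values were adjusted over these lists. An estimated correlation and the rotation test fry were run beside this test. The 3 residual degrees of freedom of the fit limit camera with an estimated correlation, but not camera with the preset value. With the preset value 15 lists were called higher and 6 lower for the mean of both hairpins, and with the estimated correlation none. Members were also counted as higher or lower by the edgeR test, over all genes and adjusted over the list alone.

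Genes were named by a rule: LINC02068; the 12 highest and 12 lowest fold changes among genes with a symbol and a mean of at least 2 CPM that were called in the same direction with both hairpins and in their mean (7173 genes, 3796 of them higher); genes called between the hairpins; up to 4 members of each list with the smallest p; protein-coding genes within 500 kb of LINC02068; and single genes set in advance, among them EPAS1, HIF1A, VHL, MYC, PPARGC1A and TFAM. Some genes and 1 list that the rule covers are not reported here. Members called against the direction of their list, and others so marked, were chosen after their values were seen.

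The alternative settings chosen then were DESeq2, RLE factors in place of TMM, no filter on low counts, a stricter filter (10 counts in 2 libraries and a mean of 1 CPM), a replicate block, a fit to only the groups compared, a test against a fold of 1.2 (glmTreat), library sizes without mitochondrial and ribosomal RNA genes, and each library left out in turn, where the lone library of a group is assumed to vary like the other groups. Total counts without TMM factors, removal of a smooth trend on exon length and GC content (15902 tested genes, 99.1%), counts thinned to the smallest library, and a fit that gives each hairpin its own control library (dispersion from the knockdown replicates) were added after the data were seen. Shared calls were compared with 20 simulations of unchanged groups that share their controls.

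The code was tested on simulated data with 16039 genes, of which 200 were changed, 100 at each fold. For the mean of both hairpins 52% of changes of 1.5-fold and 74% of 2-fold were recovered, with 21 false calls, more than the nominal share. Between the hairpins the figures were 42%, 67% and 29 false calls, and 9 genes were called with no simulated difference, so a count of 5 there can arise without any true difference. A list moved 1.5-fold was called by camera (adjusted p = 8.6e-85) and with the estimated correlation (0.00479), and 0 of 32 unmoved lists were called. Genes were drawn independently there and no gene outside the list was changed. In the data estimated correlations reached 0.845, so this simulation does not measure false list calls there.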

Results

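RNA sequencing was carried out on 786-O, an established human clear cell renal carcinoma line that lacks working VHL, the protein that marks HIF alpha subunits for destruction. Cells carried 1 of 2 short hairpin RNAs against the long non-coding RNA LINC02068 (shRNA1 or shRNA2) or a control hairpin (shControl), with 2 libraries in each of the 3 groups. The comparison addresses whether lowering LINC02068 alters transcripts of mitochondrial respiration and genes tied to drug response. Total counts per library ran from 15376448 (shRNA1 replicate 1) to 37311846 (shRNA2 replicate 1), so that a level of 1 CPM (counts-per-million) stood for 14.9 to 36.0 counts after TMM scaling. Of 60649 genes in the count table, 16039 were expressed enough to test, and they held 99.9% of the counts. The labels do not say that replicates are separate cultures, so p-values may measure technical spread only. Errors are standard errors unless marked SD, and adjusted p-values of single genes come from edgeR.

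The libraries of both hairpins differed from the control libraries in composition. ACTB, cytoplasmic beta-actin, was the most abundant gene in the 4 knockdown libraries (1.47 to 1.52% of counts), and FN1, fibronectin, in the control libraries (1.07 to 1.08%). The 10 most abundant genes took 7.37 to 7.53% of counts with the hairpins and 5.98% in the controls, and mitochondrial genes 2.57 to 2.71% and 2.30 to 2.43%. TMM factors were 0.960 to 0.969 in the knockdown and 1.07 to 1.08 in the control libraries. The first principal component held 55.3% of the variance and set the controls apart from all knockdown libraries. On the second, which held 15.1%, shRNA1 replicate 1 stood apart, at 50.4 against −23.0 to 4.99 for the other libraries.

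LINC02068 was scarce in every library. It had 20 and 32 counts in the shControl libraries, 9 and 2 with shRNA1, and 17 and 10 with shRNA2. Its level was 1.07 CPM (95% Poisson interval 0.655 to 1.66) and 1.14 CPM (0.781 to 1.61) in the controls. With shRNA1 it was 0.605 CPM (0.277 to 1.15) and 0.105 CPM (0.0127 to 0.378), and with shRNA2 0.472 CPM (0.275 to 0.756) and 0.478 CPM (0.229 to 0.880). These intervals cover counting error only. For the mean of both hairpins the log2 fold change was −1.46 ± 0.59 (edgeR adjusted p = 0.0447). Neither hairpin alone passed the threshold, at −1.70 ± 0.75 with shRNA1 (adjusted p = 0.0690) and −1.21 ± 0.68 with shRNA2 (0.148), and the levels under both hairpins did not differ detectably (−0.49 ± 0.78, adjusted p = 0.969). The call rested on single libraries. The mean was −1.02 (adjusted p = 0.124) without shRNA1 replicate 2 and −2.26 (0.00914) without shRNA1 replicate 1. It was −1.45 (0.0986) and −1.46 (0.0972) without replicate 1 or 2 of shRNA2, and −1.50 (0.160) and −1.41 (0.219) without replicate 1 or 2 of shControl. For shRNA1 alone it was −3.32 (0.0159) without shRNA1 replicate 1 and −0.85 (0.388) without shRNA1 replicate 2. DESeq2 gave −1.45 for the mean with an adjusted p of 0.107.

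**Figure D1:**
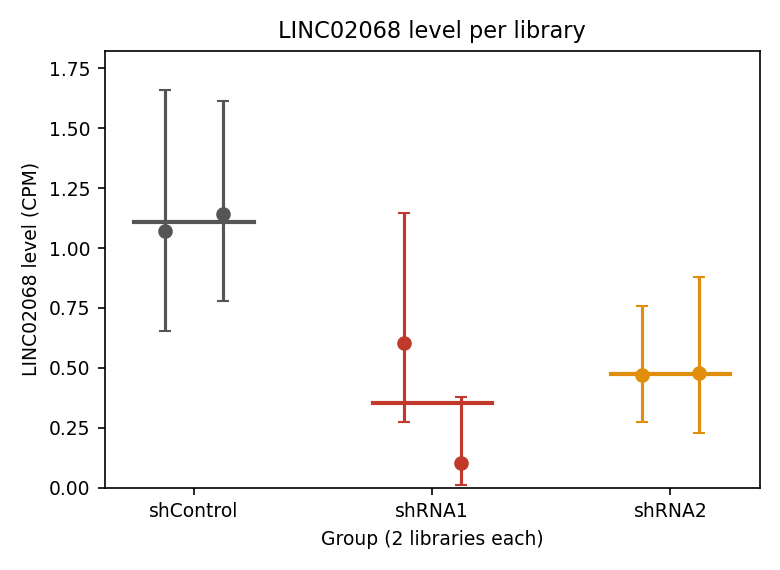
LINC02068 level in CPM (vertical axis) in each of the 6 libraries, grouped by hairpin; points are libraries, error bars are 95% Poisson intervals and horizontal lines are group means. Both control libraries lie above 1 CPM and all 4 knockdown libraries at or below 0.605 CPM.

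LINC02068 lies on the minus strand of chromosome 3, at 172560888 to 172595607 in GENCODE 29 on GRCh38, and no annotated gene overlaps it. Of the protein-coding genes within 500 kb, a pair fell with both hairpins. Over all tested genes 57.5% were called for the mean of both hairpins, so calls among so few neighbours do not set them apart. TNFSF10, which encodes the death ligand TRAIL 37.4 kb away, went from 476 CPM to 353 with shRNA1 and 349 with shRNA2 (−0.44 ± 0.03, adjusted p = 4.9e-09). ECT2, an exchange factor that drives cytokinesis 155 kb away, went from 196 CPM to 117 and 122 (−0.71 ± 0.04, adjusted p = 7.5e-10). FNDC3B, at 159 kb, was called lower by a small margin (−0.09 ± 0.03, adjusted p = 0.0327). It passed with neither hairpin alone (0.0601 and 0.0734), nor without shRNA1 replicate 1 (0.0618) or 2 (0.197), nor without shControl replicate 1 (0.0856) or 2 (0.112), and a length and GC correction turned its sign (0.03), while it was −0.25 under total counts. NCEH1, a cholesterol ester hydrolase gene 34.6 kb away, was not called (0.06 ± 0.04, adjusted p = 0.277), but was with that correction (0.17, adjusted p = 0.00358), and had the opposite sign under total counts (−0.10, not called). GHSR and SPATA16 had no counts.

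**Figure D2:**
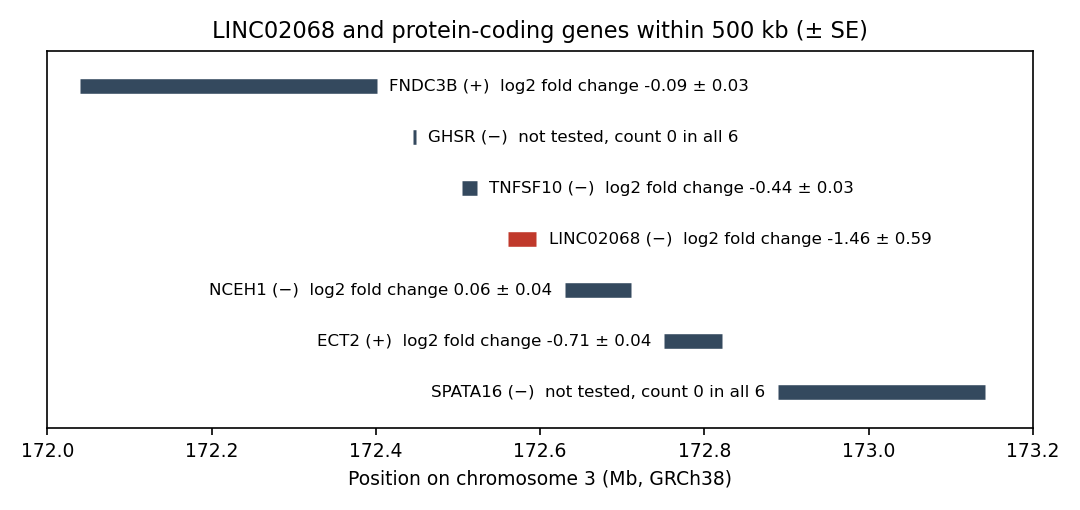
Map of chromosome 3 around LINC02068 (horizontal axis, position in Mb) with LINC02068 and its protein-coding neighbours as bars; labels give the log2 fold change of the mean of both hairpins against shControl with its standard error. TNFSF10 and ECT2 have values of −0.44 and −0.71.

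Against the controls, most tested genes differed in the mean of both hairpins by the main test. HSPA8, the constitutive HSP70 chaperone, rose from 248 CPM to 1480 with shRNA1 and 1491 with shRNA2 (2.58 ± 0.03, adjusted p = 1.3e-17). CRYAB, a small heat shock protein gene on chromosome 11, rose from 0.464 CPM to 15.2 and 13.3 (4.90 ± 0.22, adjusted p = 3.4e-11). SLC7A11, which encodes the cystine importer, fell from 184 CPM to 15.8 and 14.9 (−3.59 ± 0.05, adjusted p = 2.5e-16), and ASNS, asparagine synthetase, from 210 CPM to 18.3 and 19.2 (−3.48 ± 0.06, adjusted p = 1.3e-15). In total 4583 genes were higher and 4640 lower by the edgeR test, 57.5% of those tested, and of these 739 rose and 1298 fell by more than 1 log2 unit. DESeq2 called 8161 genes, 8106 of them shared. A test against a fold of 1.2 called 6332 of 16039, no longer most of them. With total counts in place of TMM factors, the median log2 change of all genes moved from −0.03 to −0.18 and the share of called genes that were higher from 49.7% to 36.0%, so small changes depend on the scaling.

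Among the 12 genes with the highest fold change under the naming rule were CRYAB and HSPA8. TUBB4A, a beta-tubulin of neurons and glia, rose from 0.830 CPM to 9.51 with shRNA1 and 10.5 with shRNA2 (3.55 ± 0.22), and MAP1A, a microtubule-binding protein, from 1.05 CPM to 9.82 and 9.53 (3.20 ± 0.20). NPBWR1, a neuropeptide receptor, rose by 3.47 ± 0.17 and MYH15, a myosin heavy chain, by 3.26 ± 0.40. PDE1A, a calmodulin-dependent phosphodiesterase, rose by 2.84 ± 0.23, the thioesterase gene ACOT11 by 2.49 ± 0.30 and the paralemmin PALM3 by 2.42 ± 0.23. BCYRN1, a non-coding RNA made by RNA polymerase III, rose by 2.90 ± 0.30. PCDHGC5, a protocadherin (3.04 ± 0.22), shares exons with its cluster, where PCDHGC3 reached 157 CPM. HNRNPA1L2, an intronless relative of HNRNPA1, rose from 0.411 CPM to 5.86 with shRNA1 and 3.75 ± 3.02 (SD) with shRNA2 (3.43 ± 0.67, adjusted p = 0.00501). Its call was lost without shControl replicate 1 (3.19, 0.0706) or shControl replicate 2 (3.81, 0.0625).

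Among the 12 genes with the lowest fold change were SLC7A11 and ASNS. INHBE, the inhibin beta E chain gene on chromosome 12, fell from 14.96 CPM to 0.486 and 0.404 (−4.99 ± 0.31, adjusted p = 1.0e-07), and ADM2, an adrenomedullin-like hormone, from 65.6 CPM to 4.50 and 4.61 (−3.83 ± 0.11). CHAC1, which degrades glutathione, fell from 116 CPM to 10.7 and 9.72 (−3.50 ± 0.07), and the mitochondrial folate enzyme gene ALDH1L2 from 60.8 CPM to 5.69 and 8.54 (−3.13 ± 0.08). ANGPTL2, an angiopoietin-like protein, fell by 4.66 ± 0.44, ULBP1, a ligand of the NKG2D receptor, by 4.06 ± 0.23, and SCG5, a secretory granule chaperone, by 3.81 ± 0.14. NOG, which encodes the BMP antagonist noggin, fell by 3.47 ± 0.16, the stress hormone gene GDF15 by 3.20 ± 0.17 and the phosphatase gene PTPRH by 3.19 ± 0.16.

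Most nuclear genes of the respiratory chain were higher. ATP5MC3, a membrane subunit of ATP synthase, went from 68.3 CPM to 159 with shRNA1 and 157 with shRNA2 (1.21 ± 0.04, adjusted p = 2.1e-12). NDUFS5 of complex I went from 63.7 CPM to 145 and 136 (1.14 ± 0.04, adjusted p = 6.1e-12), COX6B1 of complex IV from 29.9 CPM to 78.3 and 79.5 (1.40 ± 0.06), and UQCRQ of complex III from 46.7 CPM to 94.2 and 84.4 (0.93 ± 0.05). Of 79 nuclear subunit genes of complexes I to V, 68 were higher, 1 lower (NDUFA5, −0.17 ± 0.07) and 10 not called, with the same counts adjusted over the list alone. Their median log2 change was 0.64, or 0.49 under total counts, where 60 were higher and 3 lower. Camera, which asks whether a list moves more than the other genes, called the list higher (adjusted p = 1.7e-14), but not once the correlation between its genes was estimated from the data (adjusted p = 0.117 with an estimated correlation). By complex, the higher, lower and uncalled genes were 29, 1 and 7 for complex I (median 0.62), 9, 0 and 0 for complex III (0.47), 10, 0 and 1 for complex IV (0.72) and 18, 0 and 0 for ATP synthase (0.73), again the same adjusted over the list alone, as for every further list of the mean of both hairpins where no second count is given. Camera called these lists at adjusted p = 3.4e-08, 4.5e-04, 7.0e-05 and 4.3e-07, and none with an estimated correlation (0.117, 0.117, 0.117 and 0.151). Complex II has 4 genes, too few for the list test, of which 2 were higher. SDHC rose (0.77 ± 0.05), SDHB by less (0.23 ± 0.06, adjusted p = 0.00519), and SDHA (0.07, 0.0877) and SDHD (0.03, 0.708) were not called. SDHB lost its call without shControl replicate 2 (0.17, 0.114) and under total counts (0.07, 0.328). SDHA was called higher without shRNA1 replicate 1 (0.11, 0.0316) and after length and GC correction (0.10, 0.0150), and lower under total counts (−0.08, 0.0458).

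Most transcripts of the mitochondrial genome were higher. MT-ND3 went from 178 CPM to 325 and 301 (0.81 ± 0.05, adjusted p = 1.1e-08), MT-ND6, the light-strand gene, from 335 CPM to 472 and 466 (0.48 ± 0.03), MT-ND5 by 0.43 ± 0.03 and MT-CO3 by 0.35 ± 0.03. Of 13 genes 12 were higher and 1 was not called, the same adjusted over the list alone, with a median of 0.32 (camera adjusted p = 9.99e-04; adjusted p = 0.466 with an estimated correlation). The list call ended when the length and GC trend was removed (median 0.10, limma camera adjusted p = 0.120), and the median was 0.16 under total counts.

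Other mitochondrial genes moved both ways. PHB, the inner membrane scaffold prohibitin, rose from 77.6 CPM to 198 and 205 (1.38 ± 0.04, adjusted p = 2.3e-13), TIMM23 of the protein import channel by 1.36 ± 0.06 and TOMM40 of the outer membrane pore by 0.99 ± 0.05. BNIP3L, a mitophagy receptor, fell by 1.13 ± 0.05. Among 32 genes of biogenesis and dynamics 14 were higher, 6 lower and 12 not called (median 0.17, camera adjusted p = 0.125), against 10 higher and 11 lower under total counts (median 0.02). TFAM, the mitochondrial transcription factor, was slightly lower (−0.20 ± 0.07, adjusted p = 0.0293), a call lost without shRNA1 replicate 2 (−0.13, 0.141), shRNA2 replicate 2 (−0.18, 0.0713) or shControl replicate 2 (−0.15, 0.234), in DESeq2 (0.0746) and after length and GC correction (−0.04, 0.669). Under total counts it was called, at −0.36. PPARGC1A, the PGC-1alpha coactivator, was near the detection limit and not called (1.07 ± 0.55, adjusted p = 0.111). Mitochondrial ribosomal proteins were mostly higher, with MRPL28 at 0.92 ± 0.04 and MRPL51 at 1.05 ± 0.06. Of 75, 48 were higher, 6 lower and 21 not called, or 50 and 6 adjusted over the list alone (median 0.34, or 0.19 under total counts; camera adjusted p = 2.4e-06; adjusted p = 0.117 with an estimated correlation). OXPHOS assembly factors split into 18 higher, 8 lower and 21 not called, with COA4 at 1.18 ± 0.07 and TTC19, a complex III factor, at −1.17 ± 0.06. Their median of 0.12 (camera adjusted p = 0.131) became −0.04 under total counts. In the mitochondrial unfolded protein response 6 genes were higher, 4 lower and 4 not called. The matrix chaperonins HSPD1 (0.83 ± 0.03) and HSPE1 (1.59 ± 0.06) rose, while the list median was 0.00 (camera adjusted p = 0.370) and −0.15 under total counts.

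In central carbon metabolism more genes rose than fell. PGAM1, phosphoglycerate mutase, rose from 539 CPM to 1485 and 1505 (1.47 ± 0.03, adjusted p = 3.0e-15), LDHA, lactate dehydrogenase, from 1515 CPM to 3033 and 3005 (0.99 ± 0.02), and PFKFB3 by 1.24 ± 0.03. The glucose transporter gene SLC2A1 fell from 1490 CPM to 666 and 685 (−1.14 ± 0.03, adjusted p = 2.3e-14), and HK2, hexokinase 2, from 227 CPM to 88.7 and 91.0 (−1.33 ± 0.04; chosen after its values were seen). Of 22 tested glycolysis genes 16 were higher and 6 lower, the same adjusted over the list alone (median 0.49, camera adjusted p = 0.00478; adjusted p = 0.261 with an estimated correlation). In the TCA cycle, IDH2 (0.89 ± 0.03), IDH1 (1.03 ± 0.04), citrate synthase CS (0.78 ± 0.04) and MDH2 (0.53 ± 0.03) rose. Of 25 genes 17 were higher, 1 lower (PC, pyruvate carboxylase, −0.31) and 7 not called (median 0.41, or 0.26 under total counts; camera adjusted p = 4.4e-05; adjusted p = 0.117 with an estimated correlation).

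Most targets of hypoxia-inducible factors were lower in these VHL-deficient cells. VEGFA, the angiogenic growth factor, went from 1339 CPM to 254 and 247 (−2.42 ± 0.03, adjusted p = 1.3e-17), and NDRG1 from 1440 CPM to 501 and 505 (−1.52 ± 0.02). Of 27 tested targets none was higher, 21 were lower and 6 not called, or 22 lower adjusted over the list alone, with a median of −0.86 (camera adjusted p = 9.0e-08; adjusted p = 0.0814 with an estimated correlation). EPAS1, which encodes HIF-2alpha, fell from 550 CPM to 281 and 283 (−0.96 ± 0.03, adjusted p = 3.6e-13), and the VHL transcript from 83.4 CPM to 63.7 and 63.9 (−0.39 ± 0.06, adjusted p = 2.4e-05). HIF1A was called slightly higher (0.09 ± 0.03, adjusted p = 0.0368) and was not called, with the opposite sign, under total counts (−0.07, 0.0935). Its call was lost without shRNA1 replicate 1 (0.0620), shRNA2 replicate 1 (0.128), shControl replicate 1 (0.158) or shControl replicate 2 (0.199). Among targets of renal carcinoma drugs and linked receptors, the receptor kinase genes AXL (939 CPM to 517 and 528; −0.85 ± 0.03) and MET (−0.71 ± 0.03) fell, and 13 of 20 were lower, 3 not called and 4 higher, or 13 lower and 5 higher adjusted over the list alone (median −0.51, camera adjusted p = 0.0128; adjusted p = 0.151 with an estimated correlation). Among the higher genes were MTOR (0.85), RPTOR (0.71) and FGFR1 (0.26).

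The ATF4 and amino acid response list had the lowest median of all lists tested. SLC7A5, the large neutral amino acid transporter, fell from 1187 CPM to 288 and 300 (−2.01 ± 0.03, adjusted p = 3.6e-17), DDIT4, an inhibitor of mTORC1, from 1900 CPM to 558 and 551 (−1.78 ± 0.03), and STC2, a secreted glycoprotein also counted among HIF targets, from 370 CPM to 58.6 and 58.2 (−2.67 ± 0.04). Of 34 genes 32 were lower, 1 higher (ATF5, 1.40 ± 0.11) and 1 not called, the same adjusted over the list alone. The median was −1.76 (camera adjusted p = 2.0e-14; adjusted p = 0.0814 with an estimated correlation). The transcript of ATF4 itself fell from 410 CPM to 211 and 207 (−0.97 ± 0.04; chosen after its values were seen).

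Most NRF2 antioxidant genes rose. HMOX1, heme oxygenase 1, went from 129 CPM to 611 and 622 (2.26 ± 0.03, adjusted p = 2.5e-16). The peroxiredoxin PRDX1 rose by 1.99 ± 0.03 and AKR1C3 from 58.2 CPM to 205 and 195 (1.78 ± 0.04). SLC7A11 (−3.59), GCLC (−0.71), TXNRD1 (−0.53), ABCC3 (−0.45), GCLM (−0.33) and SOD2 (−0.14) fell. The fall of SOD2 was smaller than the shift of all genes under total counts, which is downward. Of 28 genes 18 were higher, 6 lower and 4 not called (median 0.49, camera adjusted p = 0.00333; adjusted p = 0.151 with an estimated correlation). Of 17 ferroptosis genes 9 were higher, among them the ferritin heavy chain FTH1 (2322 CPM to 3815 and 3710; 0.70 ± 0.03), 4 lower and 4 not called. Their median and camera direction were upward (0.20, or 0.05 under total counts; adjusted p = 0.408), while the mean was below 0. The endoplasmic reticulum unfolded protein response had 11 higher, 8 lower and 3 uncalled genes, or 12 and 8 adjusted over the list alone. CALR (0.87 ± 0.03), SEC61B (1.40 ± 0.06) and HSPA5, the chaperone BiP (0.47 ± 0.03), rose and HSP90B1 fell (−0.60 ± 0.03), and the median was 0.07 (camera adjusted p = 0.470), or −0.08 under total counts.

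Most genes of lipid synthesis rose. FASN, fatty acid synthase, went from 225 CPM to 773 and 794 (1.80 ± 0.04, adjusted p = 6.5e-15), and HMGCS1, which makes HMG-CoA, from 33.4 CPM to 115 and 112 (1.77 ± 0.06). LSS, lanosterol synthase, rose from 51.5 CPM to 147 and 154 (1.55 ± 0.05). In cholesterol synthesis 21 of 24 genes were higher, 0 lower and 3 not called, or 21 higher and 1 lower adjusted over the list alone (median 0.77, camera adjusted p = 1.4e-07; adjusted p = 0.0814 with an estimated correlation). In fatty acid synthesis and lipid storage 15 of 22 were higher, among them ELOVL6 (1.28 ± 0.05) and PLIN3 (0.99 ± 0.03), 1 was lower (HILPDA, −0.69) and 6 not called (median 0.28, camera adjusted p = 0.00201; adjusted p = 0.151 with an estimated correlation). Under total counts this list had 10 higher and 5 lower genes and a median of 0.13. Fatty acid oxidation was mixed. HADHA and HADHB, which encode the paired subunits of the trifunctional protein, moved apart (0.83 ± 0.03 and −0.90 ± 0.08), the regulator PPARA fell (−0.60 ± 0.06), and 11 of 19 genes were higher, 4 lower and 4 not called (median 0.29, camera adjusted p = 0.0983), against 8 higher and 6 lower under total counts (median 0.13).

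Most replication genes were higher, and the mitosis list was not called. MCM4 of the replicative helicase went from 114 CPM to 316 and 318 (1.47 ± 0.04, adjusted p = 5.4e-14), TK1, thymidine kinase, from 86.4 CPM to 232 and 247 (1.47 ± 0.04), and CLSPN, claspin, from 18.8 CPM to 64.5 and 67.2 (1.80 ± 0.07). Of 45 DNA replication and E2F genes 38 were higher, 2 lower (PRIM1, −0.49, and CDC45, −0.27) and 5 not called, the same adjusted over the list alone (median 0.81, camera adjusted p = 6.7e-11; adjusted p = 0.0814 with an estimated correlation). Of 45 mitosis genes 13 were higher, 19 lower and 13 not called. MKI67 (0.69 ± 0.03) and ANLN (0.67 ± 0.03) rose and the microtubule depolymerase KIF2C fell (129 CPM to 46.2 and 47.6; −1.46 ± 0.05). Their median was −0.02 (camera adjusted p = 0.408), 0.01 after length and GC correction, and −0.17 under total counts, where 7 were higher and 25 lower. MYC fell from 452 CPM to 236 and 244 (−0.91 ± 0.03, adjusted p = 8.5e-13), while 20 of 30 genes in the MYC list were higher, 5 lower and 5 not called (median 0.32, or 0.16 under total counts; camera adjusted p = 0.00198; adjusted p = 0.117 with an estimated correlation). Most cytosolic ribosomal protein genes were higher, with RPL6 at 0.87 ± 0.03 and RPL7A at 0.77 ± 0.03. Of 75, 71 were higher, 1 lower (RPL3, −0.07) and 3 not called, the same adjusted over the list alone. The fall of RPL3 was smaller than the shift of all genes under total counts, which is downward. The list median was 0.39, or 0.24 under total counts (camera adjusted p = 3.5e-14, and adjusted p = 0.361 with an estimated correlation).

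Most inflammatory, matrix and early response genes in the lists were lower. IL11, a cytokine of the IL-6 family, went from 160 CPM to 19.8 and 20.96 (−2.96 ± 0.07, adjusted p = 9.1e-13), IL6 from 125 CPM to 43.1 and 43.2 (−1.54 ± 0.05), VCAM1, an adhesion molecule, from 321 CPM to 126 and 138 (−1.28 ± 0.03) and the chemokine CXCL8 by 1.81 ± 0.09. Of 25 NF-kB genes 19 were lower, 2 not called and 4 higher (CCL2, 2.08, C3, 1.83, IL1B, 1.58, and NFKBIA, 0.48), with a median of −0.70 (camera adjusted p = 0.00197; adjusted p = 0.117 with an estimated correlation). FN1 fell from 10010 CPM to 5961 and 6160 (−0.72 ± 0.02), the integrin ITGB3 by 1.07 ± 0.03 and TGFBI by 0.81 ± 0.02, and 23 of 39 epithelial-mesenchymal and matrix genes were lower, 10 higher and 6 not called (median −0.31, camera adjusted p = 0.0249; adjusted p = 0.261 with an estimated correlation). Of 25 immediate early genes 14 were lower, 1 higher (ZFP36, 0.11) and 10 not called, or 15 and 1 adjusted over the list alone, with KLF4 at −2.47 ± 0.06 and FOSL1 at −1.36 ± 0.03 (median −0.34, camera adjusted p = 0.00198; adjusted p = 0.261 with an estimated correlation). Under total counts 19 immediate early genes were lower and 0 higher (median −0.49). Type I interferon genes were not called as a list. IFIT1 rose (1.53 ± 0.09) and IRF1 fell (106 CPM to 26.8 and 28.3; −1.95 ± 0.06), with 7 higher, 10 lower and 14 not called (median −0.01, or 0.02 after length and GC correction; camera adjusted p = 0.917). Under total counts 6 were higher and 12 lower (median −0.16).

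Apoptosis regulators moved both ways. PMAIP1, the BH3 protein NOXA, fell from 99.8 CPM to 25.4 and 25.9 (−1.96 ± 0.06, adjusted p = 9.5e-13). Among 28 apoptosis regulators 14 were lower, 10 higher and 4 not called (median −0.11, or −0.27 under total counts; camera adjusted p = 0.482). MCL1 (−0.64 ± 0.03) and the TRAIL receptor TNFRSF10B (−1.12 ± 0.06) fell, and AIFM1 rose (0.86 ± 0.06). Lysosome and autophagy genes split into 17 higher, 14 lower and 3 not called. ATP6V0D1 of the proton pump rose (1.45 ± 0.05), and NPC1 (−0.63 ± 0.03) and HEXA (−0.80 ± 0.04) fell. Their median was 0.06, with a mean and a camera direction below 0 (adjusted p = 0.917), and −0.09 under total counts. Of 12 tested genes in the multidrug transporter list 4 were higher, 3 lower and 5 not called. The higher genes were led by ABCG2 (1.16 ± 0.19) and MVP (0.91 ± 0.03, from 394 CPM to 720 and 759). MVP encodes a vault protein and is not a transporter. The nucleoside transporter SLC29A1 was lower (−0.87 ± 0.06). The list median was −0.10, from −0.26 under total counts to 0.00 in the highest of the settings run. Its mean and camera direction were upward (camera adjusted p = 0.917).

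**Figure D3:**
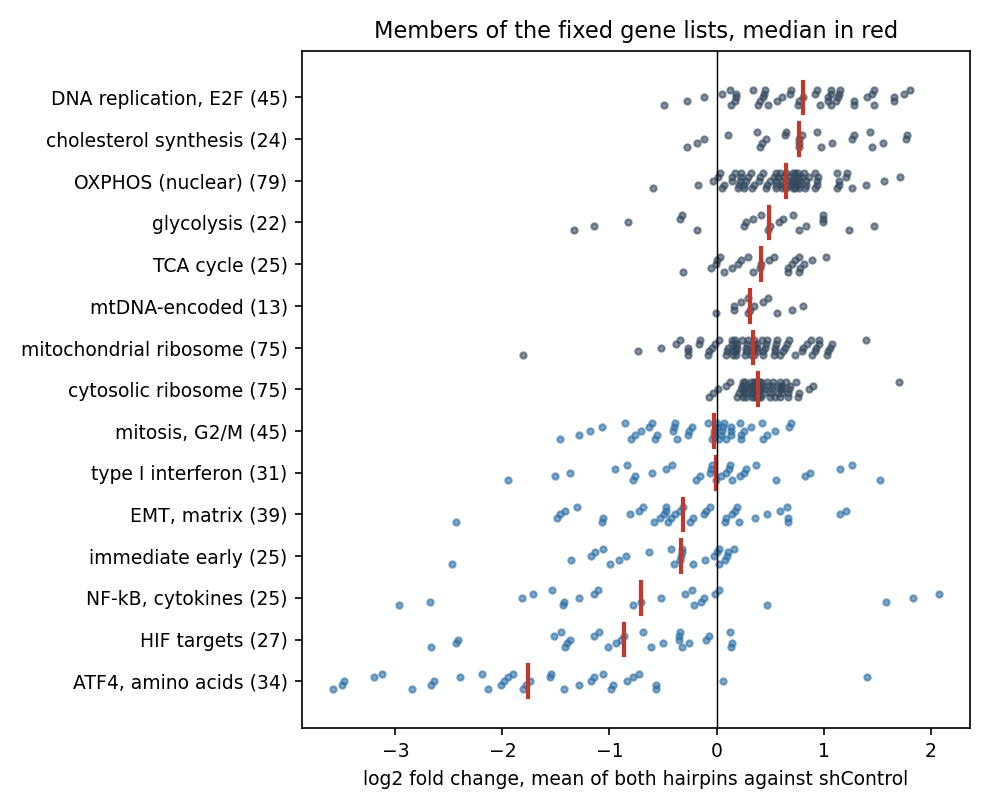
Log2 fold change of the mean of both hairpins against shControl (horizontal axis) for each tested member of 15 gene lists (vertical axis, number of members in brackets); points are genes and red bars are list medians. OXPHOS and E2F lists lie right of 0 (medians 0.64 and 0.81) and HIF and ATF4 lists left (−0.86 and −1.76); PTGS2, with no counts in shRNA1, is not drawn.

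Most markers of other cell types lay under 1 CPM, with exceptions in all lists but the erythroid one. All 11 erythroid genes lay under 1 CPM in all groups, as did 16 of 20 leukocyte, 13 of 15 endothelial, 7 of 15 fibroblast, 15 of 21 proximal tubule and 12 of 16 distal nephron genes. PDZK1, a scaffold of the proximal tubule brush border, rose from 86.6 CPM to 144 and 156 (0.79 ± 0.05), and SCNN1A, a subunit of the epithelial sodium channel, from 19.1 CPM to 40.2 and 45.9 (1.17 ± 0.08). ASS1, argininosuccinate synthase of the proximal tubule list, stood at 57.4 CPM with shRNA1 and 58.4 with shRNA2 (chosen after its values were seen). CD68 stood at 37.7, 40.9 and 38.1 CPM in shControl, shRNA1 and shRNA2, EGFL7 fell from 14.6 CPM to 7.73 and 6.81, and ACTA2 rose to 23.2 and 18.5 CPM (0.67 ± 0.11). No tested marker list was called by camera. The higher, lower and uncalled genes were 1, 2 and 2 for leukocytes (median −0.81), 0, 2 and 3 for endothelial cells (0.30), 1, 3 and 4 for fibroblasts (0.23), 2, 2 and 6 for proximal tubule (−0.07) and 3, 1 and 0 for distal nephron (1.51, too few genes for the list test). Mean and camera direction were opposite to the median for endothelial cells and fibroblasts, and camera alone for proximal tubule. The medians of these 3 lists changed sign in some settings. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had 3 higher, 2 lower and 15 uncalled genes, or 2 and 2 adjusted over the list alone (median 0.25, or 0.10 under total counts; camera adjusted p = 0.487).

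Each hairpin gave nearly the same profile. VEGFA stood at 254 CPM with shRNA1 and 247 with shRNA2, SLC7A11 at 15.8 and 14.9, and ATP5MC3 at 159 and 157. With shRNA1, 4297 genes were higher and 4103 lower than in shControl, and with shRNA2 4279 and 4183 (edgeR). With both hairpins 3911 genes were higher and 3591 lower than in the controls, against 1146 and 1070 for independent lists of these sizes, and 1 gene moved in opposite directions. Both comparisons use the same 2 control libraries. In simulated unchanged groups that share their controls, at most 3 genes were called in each direction, and the correlation of the fold changes across genes was 0.490 on average against 0.798 in the data. When each hairpin had its own control library, that correlation in the data was 0.555, and 0.528 with the controls exchanged. With a separate control library for each hairpin, 3168 genes were higher and 2746 lower with both, against 856 and 707 for independent lists. With the controls exchanged the counts were 3116 and 2722. Of 9505 genes with a mean of 10 CPM or more, 99.4% differed between the hairpins by less than 0.5 log2 units. The OXPHOS list had 68 higher and 0 lower genes with shRNA1, or 69 and 0 adjusted over the list alone (median 0.66, camera adjusted p = 3.7e-15; adjusted p = 0.114 with an estimated correlation) and 67 higher and 1 lower with shRNA2 by either adjustment (median 0.65, camera adjusted p = 3.6e-14; adjusted p = 0.122 with an estimated correlation).

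**Figure D4:**
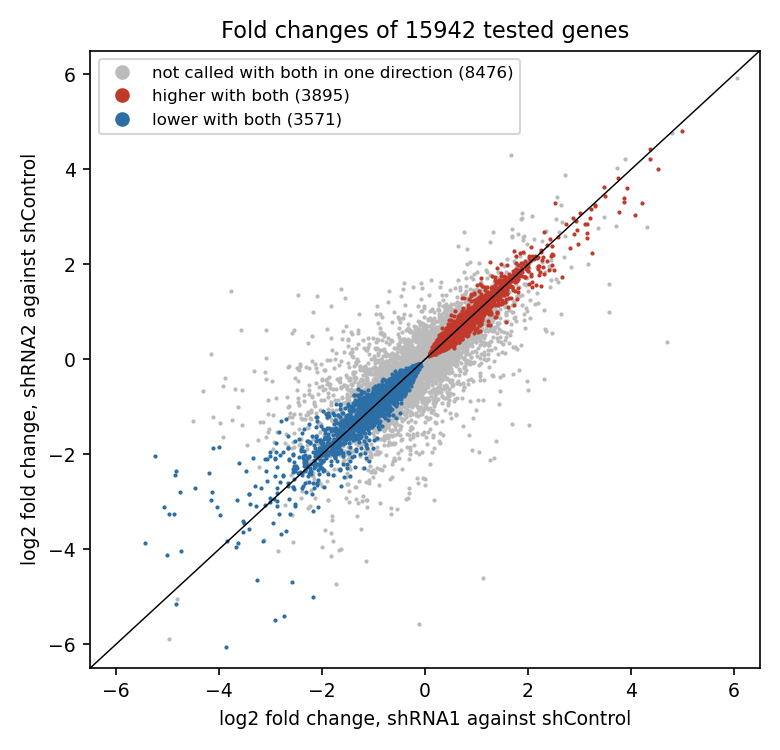
Log2 fold change of shRNA1 (horizontal axis) and of shRNA2 (vertical axis) against shControl, 1 point per gene for 15942 tested genes; red and blue points are called higher or lower with both hairpins, and the line marks equal change. Called genes lie along the line; 97 genes with a group at 0 counts are not drawn.

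Tested directly, 5 genes differed between shRNA1 and shRNA2 by edgeR, 1 higher and 4 lower with shRNA1, with 873 at an unadjusted p under 0.05. DESeq2 called 17. CPT1B, which encodes the muscle form of the carnitine palmitoyltransferase that admits fatty acids to mitochondria, had 1.73 CPM with shRNA1, 6.36 with shRNA2 and 6.46 in shControl (−1.88 ± 0.27, adjusted p = 0.0179). Its call was lost without shRNA1 replicate 2 (−1.70, 0.116), and it overlaps the readthrough gene CHKB-CPT1B. UGT1A9, a glucuronosyltransferase that shares exons with its cluster on chromosome 2, had 7.95 CPM with shRNA1, 26.6 with shRNA2 and 14.2 in shControl (−1.73 ± 0.18, adjusted p = 0.00149), and was the gene that fell with shRNA1 (−0.83, 0.00169) and rose with shRNA2 (0.90, 4.6e-04). ELOCP2, a pseudogene on chromosome 15, had 0 counts in both shRNA1 libraries, 129 and 70 with shRNA2 and 55 in each control. With a floor of 3 counts over the group, it was at least 39.3-fold lower than with shRNA2 and at least 27.8-fold lower than in shControl (adjusted p = 3.0e-04 between the hairpins). CTD-2192J16.20, a transcript over ZNF490 and ZNF564, had 0 counts with shRNA1, 148 and 49 with shRNA2 and 93 and 153 in the controls, at least 36.6-fold and 59.2-fold lower (adjusted p = 3.0e-04). LA16c-431H6.6, which overlaps CRAMP1 and JPT2, had 9.21 CPM with shRNA1, 1.45 with shRNA2 and 2.31 in shControl (2.65 ± 0.28, adjusted p = 5.5e-04). Of the gene lists, OXPHOS was called higher with shRNA1 than with shRNA2 by 0.04 in the median (camera adjusted p = 0.0207; adjusted p = 0.937 with an estimated correlation), with none of its 79 genes called. Simulated changes between these groups were recovered for 42% of genes at 1.5-fold and 67% at 2-fold.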

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

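The tests for another cell line and for library scaling were chosen only after the result was seen, the latter in place of a median relative to all genes, which no scaling can move, and the length and GC correction, thinning and scaling to total counts were added after the data were seen. A difference between groups marked 5 genes, each by a direct edgeR test of shRNA1 against shRNA2. ELOCP2 was at least 39.3-fold lower with shRNA1 and CTD-2192J16.20 at least 36.6-fold lower, both from 0 counts in the shRNA1 libraries. CPT1B differed by −1.88 log2 units, LA16c-431H6.6 by 2.65 and UGT1A9 by −1.73. The simulation with no difference between hairpins gave 7.5 calls on average and at most 13, so the number of calls is not above what unchanged groups give. Of these genes, 4 overlap or share exons with other genes, so that reads of a neighbour may be counted for them. Splitting the 4 knockdown libraries in each of the 3 ways gave 5 genes for the real hairpins and 7 and 5 for the others, so 3 of 3 splits gave at least as many as the real one. At an unadjusted p under 0.05 the counts were 873 for the real hairpins and 793 and 629 for the others. With 3 splits these counts leave open whether hairpin identity adds to the spread.

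The first pattern weighed is the higher level of OXPHOS subunit genes. Removing the trend on transcript length and GC content left a median of 0.59 (limma camera adjusted p = 2.2e-13), so that trend is not the whole cause. Short abundant genes rose too, with a median of 0.26 (central 95% 0.11 to 0.38) in 10000 random lists matched on length and expression, but the OXPHOS median of 0.64 was at percentile 100 of them (highest 0.53). The OXPHOS median was lowest under total counts, at 0.49, so none of the 4 scalings run accounts for it. Its bootstrap 95% interval over member genes, not libraries, was 0.40 to 0.57. The call was lost with an estimated correlation (limma camera adjusted p = 0.117), a test that rests on 3 residual degrees of freedom. Lists with a negative estimated correlation, such as ATF4 (−0.0131) and complex III (−0.0873), lost their calls too. Correlation between genes is therefore not the whole cause of such losses. Some lists had higher medians than OXPHOS: DNA replication and E2F targets (0.81), cholesterol synthesis (0.77) and proteasome subunits (0.81, chosen after the top genes were seen). Other lists moved less or fell. The rise therefore does not single out OXPHOS genes. What stays open is whether the list call would hold with more libraries, and the culture batch of the controls.

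The second pattern is the profile that both hairpins share against the controls. At equal depth, with 15273 genes tested, the number of calls was 97.4% of the main number and 8729 of the main calls (94.6%) were called again, so a difference in depth is not the whole cause. A different cell line in one group would switch many genes on or off, but 2 genes had 10 CPM or more on one side and under 0.1 CPM in every library of the other: CH507-9B2.4 (0 in controls, 22.5 CPM in knockdown) and RP5-1042K10.14 (10.3 CPM in controls, 0 in knockdown). A culture or library batch cannot be told apart from the knockdown, since the component that holds 55.3% of the variance parts control from knockdown libraries and each group may have been handled as a unit. The low level of LINC02068 in all groups and a fall called in the mean alone leave open how much of the profile follows from it.

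The third pattern is the lower level of ATF4 and amino acid response genes. The median was −1.76 or lower over 4 scalings, so none of these accounts for it. With RLE factors, which gave the highest median, the bootstrap 95% interval over member genes was −2.01 to −1.17. The median was −1.80 after removal of the length and GC trend, so that trend is not the whole cause. Amino acid stress in the control cultures at harvest, such as spent medium, would raise the tRNA synthetase genes that ATF4 drives in the controls. The 20 cytosolic synthetase genes had a median of −0.49, with 12 lower and 6 higher, among the latter HARS1 (1.08). The list was not called (limma camera adjusted p = 0.0610). Some members, such as AARS1 (−1.28), GARS1 (−0.78) and EPRS1 (−0.57), also belong to the ATF4 list, so they repeat the pattern and do not test it. A fall would follow from such stress and also from lower ATF4 activity after knockdown, so these cannot be told apart.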

How the results depend on the processing

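Total counts, length and GC correction, thinning and separate controls were chosen after the data were seen. The number of genes called for the mean of both hairpins ran from 6332 (fold over 1.2) to 9426 (total counts), with 7557 to 9020 when 1 library was left out, and the counts for each hairpin and for both together stayed within 1.5 times the main count in every setting run. DESeq2 kept 8106 of these genes (87.9%), and a replicate block, with 9170 calls of its own, kept 9032 (97.9%). Replicate numbers do not pair libraries (correlations of replicate deviations 0.0107, −0.0290 and −0.00123).

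The 5 genes between the hairpins became 17 with DESeq2, 69 with no filter, 9 with a replicate block, 16 with only the groups compared, and 12 to 31 when 1 library was left out, where 1 fewer library changes the dispersion estimates; the cause was not tested otherwise. All 5 were called in each of these except CPT1B without shRNA1 replicate 2.

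LINC02068 had few counts, 2 to 32 per library. For shRNA1 it passed the threshold with only the groups compared (−1.72, adjusted p = 0.0498), total counts (−1.85, 0.0494) and thinned counts (−1.73, 0.0399), and ran from −3.32 to −0.85 without 1 library. For the mean it missed the threshold with DESeq2 (−1.45, 0.107), a replicate block (−1.52, 0.0506) and a fold over 1.2 (−1.46, 0.0698, a stricter test by construction), and ran from −2.26 to −1.02 without 1 library. The cause was not tested for the others.

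Among named genes called in the main or the other setting, signs turned for SDHA (−0.083) and HIF1A (−0.068) with total counts, by the shift of −0.16 in all genes. The sign of FNDC3B (0.030) turned with the length and GC trend removed. Turns of genes called in neither setting, such as NCEH1, are not counted here. OXPHOS lost its call with an estimated correlation (limma camera adjusted p = 0.117), a setting that cannot move its median of 0.64. That median ran from 0.61 to 0.68 without 1 library. Of 38 lists, 21 were weaker with an estimated correlation, a test on 3 residual degrees of freedom. Among them were lists with a negative estimate, such as cholesterol synthesis (−0.0380), so shared variation between genes is not the whole cause. With fry 13 were stronger. With length and GC removed 1 (mitochondrial DNA-encoded) was weaker, with no filter 1 was stronger, and with a replicate block 38 were the same. Of 183 named gene results, all kept their call with RLE factors, 179 with DESeq2, 177 at a fold over 1.2, and 2 to 10 lost it without 1 library.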

Other observations

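The gene lists of this part, apart from the histone genes, were chosen only after the top genes were seen. Their p-values are adjusted over these 7 lists, or over 6 for members not seen before. Lists set in advance were adjusted over 38, so adjusted values of the 2 kinds cannot be compared. Before adjustment, camera with an estimated correlation gave p = 0.00267 for the ATF4 list and 0.0082 for the E2F list. It gave 0.00416 for heat shock chaperones, 0.0138 for proteasome and 0.0209 for spliceosome genes. Most heat shock chaperone and proteasome genes rose. HSPA1A, the inducible HSP70, went from 4.16 CPM to 16.96 with shRNA1 and 17.5 with shRNA2 (log2 fold change 2.06), HSP90AA1 from 450 CPM to 1955 and 1932 (2.11), HSPB1 rose by 1.71, the co-chaperones STIP1 and DNAJA1 by 1.39 and 1.36, while the regulator HSF1 was not called (0.08, edgeR adjusted p = 0.353). All 32 proteasome subunit genes were higher (median 0.81; limma camera adjusted p = 3.8e-13, adjusted p = 0.0484 with an estimated correlation), with PSMB6 at 1.77 and PSMD1 at 1.46. Of 41 spliceosome genes 36 were higher and 2 lower (median 0.63, limma camera adjusted p = 1.1e-09, adjusted p = 0.0487 with an estimated correlation), with DHX9 at 1.88 and SNRPD3 at 1.21. Of the 37 not seen before, 32 were higher and 2 lower (median 0.61, limma camera adjusted p = 1.5e-08, adjusted p = 0.0349 with an estimated correlation).

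Aminoacyl-tRNA synthetases had medians of opposite sign by compartment. Of 20 cytosolic ones 12 were lower and 6 higher, with YARS1 at −1.55, AARS1 at −1.28, CARS1 at −1.24 and RARS1 at 1.16 (median −0.49; limma camera adjusted p = 0.0610, adjusted p = 0.191 with an estimated correlation). Of 17 mitochondrial ones 11 were higher and 1 lower, with LARS2 at 1.41 and CARS2 at 1.35 (median 0.33; limma camera adjusted p = 0.0103, adjusted p = 0.191 with an estimated correlation).

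A heat shock response shared by the class was tested on 26 chaperone genes whose values had not been looked at. Their median was 0.83 (bootstrap 95% interval over member genes 0.56 to 0.95, limma camera adjusted p = 4.8e-09, adjusted p = 0.0349 with an estimated correlation). Of these genes 22 were higher and 1 lower, which met the bound set for such a response and does not say what started it. Unseen members of the proteasome (median 0.81) and spliceosome (0.61) lists rose too, so the rise does not single out a heat shock response. With the members seen before, 27 of 31 were higher and 1 lower (median 0.90; limma camera adjusted p = 1.2e-11, adjusted p = 0.0291 with an estimated correlation).

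Higher BMP signalling was considered because ID1 (1.93), ID3 (2.16) and ATOH8 (1.90) rose and NOG fell. In 12 other targets the median was 0.076 (bootstrap 95% interval over member genes −1.15 to 0.68, limma camera adjusted p = 0.784). Of these 4 were higher, among them SMAD6 (0.95) and ID2 (0.93), and 5 lower, among them HEY1 (−1.71) and RUNX2 (−2.06). The reading of this test was changed after its value was seen: the median met the bound set against the hypothesis, but not by more than its spread, so the test leaves it open. Over all 16 targets 7 were higher and 6 lower (median 0.36, limma camera adjusted p = 0.592). Their mean was below 0 and includes a fitted value for UNC5B, which had no counts with shRNA1.

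More RNA without a poly(A) tail in the knockdown libraries was considered because BCYRN1 (2.90), RN7SK (1.74) and RMRP (1.90) rose. The median of replication-dependent histone genes was 0.25 with members moving both ways, and RN7SL1 (−1.60) and RN7SL2 (−1.78) fell, so the test leaves it open. Over the 5 RNA polymerase III transcripts the median was 1.74 (limma camera adjusted p = 0.440). It includes BCYRN1, RN7SK and RMRP, whose rise prompted the question, so it does not test it. The 2 transcripts not seen before, RN7SL1 and RN7SL2, had a median of −1.69.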
